A study of Mus musculus with 13 samples.

How the data were processed

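The 13 libraries were bulk RNA sequencing libraries of sorted gamma delta intraepithelial lymphocytes from the small intestine of wild-type mice. Per the labels' protocols, mice received 200 µg of UC7-13D5, a hamster antibody against the gamma delta T cell receptor (TCR), or Armenian hamster IgG by intraperitoneal injection 48 and 24 hours before cell isolation. The design text gives 48 or 24 hours before IFNa or PBS, so whether each mouse received both doses is unclear. They then received 1 µg of interferon alpha (IFNa) or phosphate buffered saline (PBS) intravenously 5 hours before isolation. RNA was extracted with an RNeasy kit and libraries were made with a SMART-Seq HT kit, per the labels' protocols. The groups, named IgG-PBS, IgG-IFNa, UC7-PBS and UC7-IFNa, were taken from the sample titles and held 3, 4, 3 and 3 libraries. Whether a library came from 1 mouse or several was not given in the sources used here.

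The submitters' processing notes name STAR 2.7.8a, Partek and DESeq2 and the genome build mm39, without saying which step each performed. The deposited count table held expected counts per gene, not scaled between libraries, as made by the authors. It listed 21084 genes, of which 14778 were marked protein-coding, and 38.0% of its values were not whole. No gene in it had a total under 10. The authors' second table held a signal per gene and library: normalized counts for 11281 genes. Within each library the ratio of estimated to normalized counts was 1 constant, to a relative spread of 9.34e-06, so that table was the first divided by 1 factor per library. The largest estimated count of any gene it left out was 100, and every gene it kept reached at least 100 in some library. It served only for an alternative. Gene symbols and mm39 positions came from the deposited tables, and 70 entries whose symbol was shared or absent were treated by their Ensembl identifier.

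Library totals ran from 19867201 to 26895876 estimated counts and are given per library with the results. Estimated counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr by group at its minimum count of 10, leaving 15835 genes. Library sizes were scaled by TMM (trimmed mean of M values). One negative binomial model with a coefficient per group was fitted to all 13 libraries with robust quasi-likelihood dispersion (edgeR 4.0.16, R 4.3.3). The contrasts were IFNa against PBS after IgG, IFNa against PBS after UC7-13D5, UC7-13D5 against IgG with PBS, UC7-13D5 against IgG with IFNa, and the interaction of antibody and IFNa. Tests were two-sided quasi-likelihood F tests with Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Levels other than the per-library Xist and Y-linked values are TMM-scaled CPM, as mean ± SD over the libraries of a group.

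There were 30 gene lists, written from general knowledge of interferon responses, TCR signalling and intestinal lymphocytes, and these, the tests, the groups and the first set of alternatives were fixed before the data were examined. The lists covered type I interferon-stimulated antiviral genes, interferon-inducible GTPases, interferon receptor signalling and feedback, MHC class I antigen processing, gamma delta TCR constant regions and CD3, gamma delta TCR variable segments, TCR proximal signalling, TCR-induced early response, cytotoxic effectors, natural killer receptors, inhibitory receptors, tissue residency, lymphocyte recirculation, cytokines and repair factors, interleukin 15 signalling, apoptosis, cell cycle, glycolysis, oxidative phosphorylation, the unfolded protein response, dissociation and heat-shock stress, cytosolic ribosomal proteins and mitochondrially encoded transcripts. Another 7 lists held markers of other cell types: absorptive enterocytes, secretory epithelium, alpha beta T cells, B and plasma cells, myeloid and dendritic cells, innate lymphoid cells, and stroma and endothelium. Of the oxidative phosphorylation list, 11 members were matched through synonyms. Each list with at least 5 tested members was tested with camera on voom values (limma 3.58.1) at the preset correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over the lists of a contrast. Members past the threshold were counted both over all genes and adjusted over the list alone. A list score was the mean over its members of log2 CPM centred on all libraries.

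Named genes followed a rule. In each contrast they were up to 12 genes with the largest rise and up to 12 with the largest fall among genes past the threshold, with a mean log2 CPM of at least 3, no overlap between the libraries of the groups compared, and a symbol other than a clone name. Added to these were up to 4 members of each list with the smallest p, and fixed genes in every contrast, which included Trdc, Trgc1, Trgc2, Cd3e, Itgae, Cd8a, Isg15, Ifit1, Irf7, Mx1, Nr4a1, Gzma and Gzmb. Single-library omissions were run for the list results of the contrasts above, for the genes chosen by size and for the fixed genes. They were not run for the list examples, nor for the lists of the averaged difference described below.

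The alternatives were median-of-ratios (RLE) scaling, no filter beyond a minimum of 1 count, a filter of 5 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma voom with quality weights, a fit of only the groups compared, the replicate number as a block, dispersion without robust estimation, limma trend on the authors' normalized counts with a pseudocount of 1, and each library left out in turn. After the data were seen, 6 alternatives were added: a covariate for the share of male RNA from Xist and Y-linked transcripts, in the gene tests and in the list tests, omission of the IgG-IFNa libraries with Y-linked transcripts, omission of those with almost none, omission of UC7-IFNa library 2 together with the covariate, and the difference between antibodies averaged over PBS and IFNa. Libraries were also regrouped 190 times, 100 of them for the interaction and the averaged difference, and the genes past the threshold counted each time. Intervals of median shares came from 2000 bootstrap draws over genes, which are correlated, and do not cover the spread between libraries. GC content per gene came from reference transcripts of an earlier mouse build and entered 1 test only.

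The fit was tested on simulated data with the spread and depth of these libraries and 200 changed genes, besides the MHC class I list, which was doubled in the changed group. Genes were drawn independently around 1 shared mean profile, without an outlying library or a mixture of sexes. The recovery and false calls below hold for that setting only. With 4 libraries against 3, edgeR recovered 54% of genes changed by 1 log2 unit and 81% of genes changed by 2, with 13 false calls. With 3 against 3, in the design of IFNa against PBS after UC7-13D5, it recovered 39% and 76% with 3 false calls, and the interaction test recovered 16% and 64% with 10 false calls. Over the contrasts edgeR made 3 to 13 false calls, limma voom with quality weights 2 to 9 and the DESeq2 Wald test 26 to 35. No library or sample was left out of the principal fit. Alternative splicing, antigen receptor rearrangement and genetic variants were not analysed here, since the tables hold sums per gene.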

Results

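The data were transcript counts of gamma delta intraepithelial lymphocytes sorted from the mouse small intestine, a T cell population that lives between the epithelial cells of the gut. The 2 by 2 design asked how these cells respond to IFNa, a type I interferon, and whether that response differs when their TCR is bound by the antibody UC7-13D5. There were 3 IgG-PBS, 4 IgG-IFNa, 3 UC7-PBS and 3 UC7-IFNa libraries. Total estimated counts were 25808105, 24243111 and 26183710 in IgG-PBS libraries 1 to 3, and 25163216, 26895876, 25414132 and 26160360 in IgG-IFNa libraries 1 to 4. They were 23075475, 24229298 and 25499253 in UC7-PBS libraries 1 to 3, and 25012935, 19867201 and 22232486 in UC7-IFNa libraries 1 to 3.

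The libraries carried the transcripts of gamma delta intraepithelial lymphocytes in every group. Trdc (ENSMUSG00000104876, mm39 chromosome 14, 54380308 to 54386325), the constant region of the TCR delta chain, stood at 181 ± 25.2 CPM in IgG-PBS (SD, n = 3), 179 ± 12.2 in IgG-IFNa (n = 4), 205 ± 5.55 in UC7-PBS (n = 3) and 191 ± 11.7 in UC7-IFNa (n = 3). Trgc2 (ENSMUSG00000076752, chromosome 13, 19488819 to 19491721), a gamma chain constant region, stood at 928 ± 24.1, 877 ± 61.8, 978 ± 75.1 and 1100 ± 80.1 CPM in the same order. Gzma, the transcript of the protease granzyme A, alone took between 2.29% and 4.10% of a library's counts, and Gzmb, that of granzyme B, between 1.07% and 1.42%.

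The libraries differed in measures that the groups do not name, and these are given here because they recur with the gene groups. Xist, the RNA that silences the inactive X chromosome of female cells, stood, in CPM without TMM scaling, at 345, 265 and 286 in the IgG-PBS libraries and at most at 1.08 CPM in the UC7-13D5 libraries. On the same scale the sum of 4 Y-linked transcripts was at most 0.310 CPM in IgG-PBS libraries and at least 132 CPM in UC7-13D5 libraries. IgG-IFNa libraries 1 and 2 had 204 and 215 CPM of Xist with 2.15 and 1.67 CPM of Y-linked transcripts. IgG-IFNa libraries 3 and 4 held both kinds of transcript, with 68.3 and 23.4 CPM of Xist and 210 and 320 CPM of Y-linked transcripts. The difference between antibodies therefore coincided with a difference in sex-linked transcripts. UC7-IFNa library 2 stood apart on the axis that carried 25.4% of the variance (108 against -26.5 to 11.1 in the others). It had 1.14% of its counts on the 18S ribosomal RNA gene Rn18s, against 0.0866% to 0.333%, and its log2 CPM correlated with its group mates at 0.940 and 0.943, where UC7-IFNa libraries 1 and 3 correlated at 0.984 across genes. Mitochondrial transcripts took 1.18% ± 0.480 of counts in IgG-PBS, 1.26% ± 0.202 in UC7-PBS, 0.668% ± 0.0969 in IgG-IFNa and 0.819% ± 0.355 in UC7-IFNa.

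**Figure D1:**
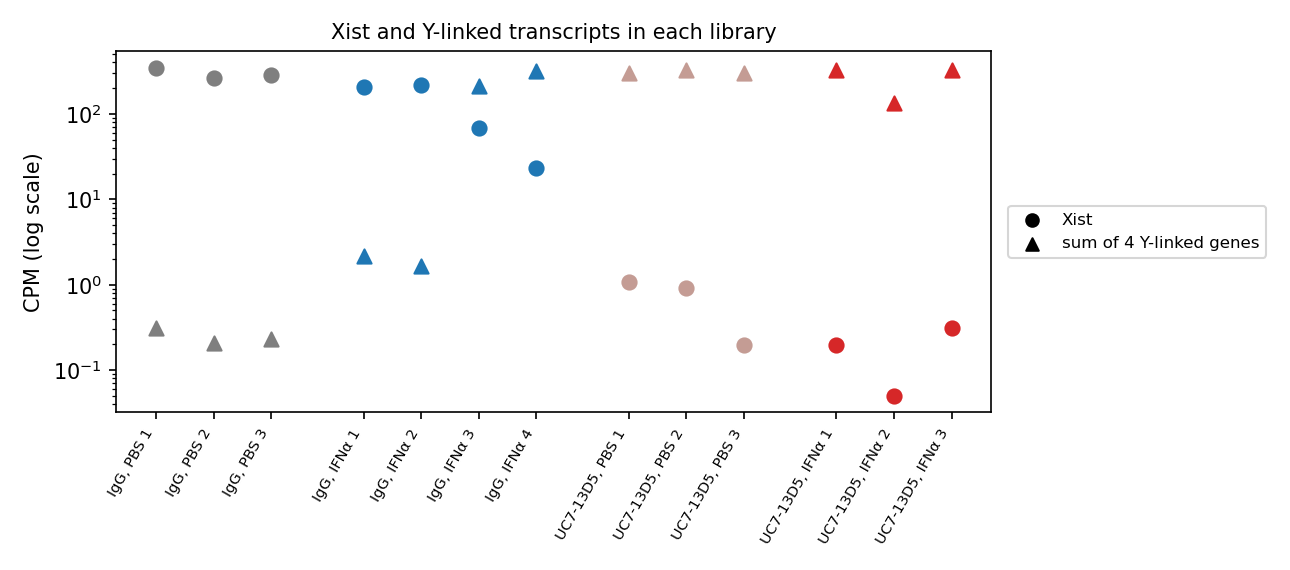
Xist and the sum of 4 Y-linked transcripts (CPM without TMM scaling, log axis), in each of the 13 libraries by group. IgG-PBS libraries hold Xist and at most 0.310 CPM of Y-linked transcripts, UC7-13D5 libraries the reverse, and IgG-IFNa libraries 3 and 4 hold both.

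IFNa against PBS after IgG asked what IFNa does in these cells when their receptor is not bound. Ifit3, an antiviral protein (ENSMUSG00000074896, chromosome 19, 34560931 to 34566131), rose from 4.70 ± 1.32 to 48.7 ± 12.5 CPM (n = 3 and 4), a log2 fold change of 3.37 (SE 0.33, edgeR adjusted p = 0.000135). Irf7, a transcription factor that amplifies interferon responses (ENSMUSG00000025498, chromosome 7, 140842619 to 140846394), rose from 141 ± 16.7 to 371 ± 14.9 CPM, by 1.40 (SE 0.16, edgeR adjusted p = 0.000793). Jun, a subunit of the AP-1 transcription factor (ENSMUSG00000052684, chromosome 4, 94937271 to 94940459), fell from 1556 ± 165 to 560 ± 221 CPM, a log2 fold change of -1.47 (SE 0.26, edgeR adjusted p = 0.0159). Of 15835 genes, 98 rose and 33 fell, and 1723 had an unadjusted p under 0.05. The groups did not overlap for any of the 131 called genes, nor for 14.0% of the tested genes, where chance gives 5.71%.

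Of the 53 tested type I interferon-stimulated antiviral genes, 21 rose and none fell, and adjusted over the list alone 40 rose. Their median log2 fold change was 1.10 (camera adjusted p = 1.31e-45, and adjusted p = 0.0215 with an estimated correlation). Among them Ifi27l2a rose by 3.27 (SE 0.38), Rtp4, a chaperone-like antiviral factor, by 1.87 (SE 0.21), and Bst2, which tethers budding virions, by 1.69 (SE 0.21). Outside the lists, Ifi213, of the nucleic acid sensing family of Ifi genes, rose by 2.94 (SE 0.25), and Rnf213, a large ubiquitin ligase, by 2.17 (SE 0.20). The interferon-inducible GTPases had a median of 0.56, with 1 of 16 past the threshold and 9 adjusted over the list alone (camera adjusted p = 1.54e-11, and adjusted p = 0.202 with an estimated correlation). The 1 called was Gbp10, a guanylate-binding protein, at 2.77 (SE 0.40). Interferon receptor signalling and feedback had a median of 0.19 with 4 of 20 higher, or 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.78e-06, and adjusted p = 0.202 with an estimated correlation). Among them were Usp18, the deconjugase of ISG15 that dampens the receptor, at 2.22 (SE 0.29), Irf9 at 1.10 (SE 0.14) and Stat3 at 0.93 (SE 0.18). MHC class I antigen processing had a median of 0.15 with 1 of 23 higher, also 1 adjusted over the list alone (camera adjusted p = 0.00155, and adjusted p = 0.202 with an estimated correlation). That gene was H2-T23, which encodes the ligand of the NKG2A receptor, at 0.64 (SE 0.13).

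Not every interferon-stimulated gene passed after IgG. Isg15, a ubiquitin-like antiviral protein, had a log2 fold change of 0.76 (SE 0.21, edgeR adjusted p = 0.131), and Mx1, a GTPase that blocks viral replication, one of 1.15 (SE 0.40, adjusted p = 0.262), from 1.33 ± 0.598 to 2.96 ± 1.28 CPM. Ifit1 passed at 1.86 (SE 0.35), but not without IgG-IFNa library 2 (1.68) or 3 (1.94) or IgG-PBS library 1 (1.91), 2 (1.78) or 3 (1.90). Oas3, a sensor of double-stranded RNA, passed at 2.68 (SE 0.43), but not without IgG-PBS library 1 (2.69) or 2 (2.46). The genes Ifit3, Ifi27l2a, Ifi213, Gbp10, Rnf213, Rtp4, Bst2 and Irf7 passed without any single library.

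**Figure D2:**
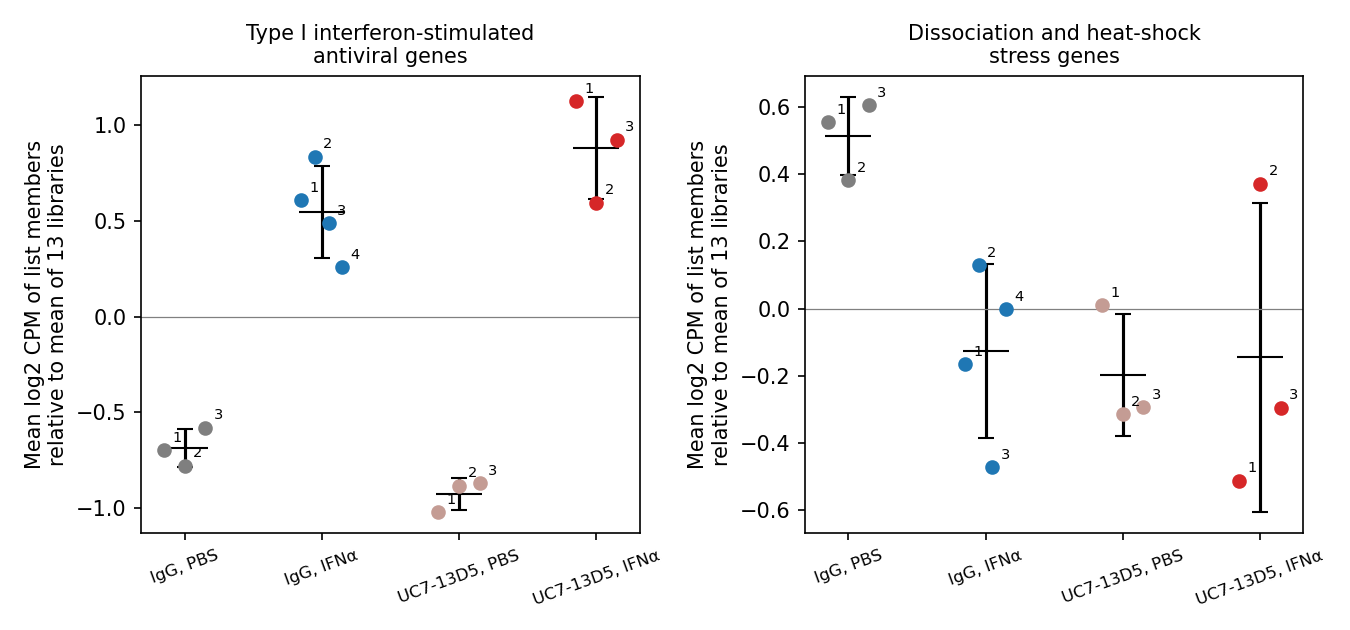
Mean score of the antiviral list and of the dissociation and heat-shock list (log2 CPM centred on all libraries, averaged over list members) in each library by group, with the group mean and SD. Antiviral scores average -0.69 in IgG-PBS, 0.55 in IgG-IFNa, -0.93 in UC7-PBS and 0.88 in UC7-IFNa, and the heat-shock score is highest in IgG-PBS at 0.51.

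The TCR-induced early response list, genes that antigen receptor signals switch on, had a median of -0.30 over 35 genes (camera adjusted p = 0.00645, and adjusted p = 0.272 with an estimated correlation). It lost its call without IgG-PBS library 1 (-0.24, camera adjusted p = 0.0582). In it 2 genes rose and 3 fell, or 4 and 10 adjusted over the list alone. The 3 were Ifng, the type II interferon (ENSMUSG00000055170, chromosome 10, 118276951 to 118281797), from 72.9 ± 9.63 to 29.2 ± 6.97 CPM (log2 fold change -1.32, SE 0.24), Myc at -0.99 (SE 0.20) and Cd69 at -0.88 (SE 0.19). The 2 that rose were Crem, a cAMP-responsive transcription factor, at 1.17 (SE 0.19) and Nfkb2 at 0.93 (SE 0.18). Ifng did not pass without IgG-IFNa library 3 (-1.28) or 4 (-1.19) or without IgG-PBS library 1 (-1.21), 2 (-1.36) or 3 (-1.39). Nr4a1, a direct reporter of TCR signals, had -0.85 (SE 0.22, edgeR adjusted p = 0.104).

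The recirculation and naive-like list had a median of -0.48 over 16 genes with 1 lower, or 1 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.00504, and adjusted p = 0.21 with an estimated correlation). The 1 was Il7r, the interleukin 7 receptor, from 52.5 ± 14.4 to 19.1 ± 6.30 CPM (-1.46, SE 0.27), which did not pass without IgG-IFNa library 1 (-1.42), 3 (-1.45) or 4 (-1.30) or IgG-PBS library 2 (-1.37) or 3 (-1.31). Interleukin 15 signalling had a median of 0.28 over 14 genes with Pim2 (0.78, SE 0.15) and Il21r (0.75, SE 0.16) higher and Cish, a feedback inhibitor of STAT5, lower (-0.99, SE 0.18), and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00645, and adjusted p = 0.202 with an estimated correlation). The serpins Serpinb9 (0.85, SE 0.16) and Serpinb6b (0.72, SE 0.15), inhibitors of granzymes, rose within a cytotoxic list that did not pass as a whole. Dgat1, which completes triglyceride synthesis, rose by 1.61 (SE 0.23) from 273 ± 60.6 to 834 ± 266 CPM and passed without any single library. Slc16a3, a lactate transporter, rose by 0.75 (SE 0.14), Trib3, a pseudokinase of the stress response, by 1.27 (SE 0.18) and Xaf1, an apoptosis-associated factor also on the antiviral list, by 1.28 (SE 0.15).

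The dissociation and heat-shock list had a median of -0.49 over 23 genes with 4 lower, or 7 adjusted over the list alone (camera adjusted p = 8.1e-12, and adjusted p = 0.202 with an estimated correlation). Besides Jun these were Fos, its AP-1 partner, from 1507 ± 193 to 745 ± 113 CPM (-1.02, SE 0.14), Zfp36, which degrades cytokine transcripts (edgeR adjusted p = 0.0174), and Ier5 (-0.72, SE 0.14). Jun did not pass without IgG-IFNa library 4 (-1.43) or IgG-PBS library 1 (-1.40) or 3 (-1.46), and Fos passed without any single library. Cell isolation itself induces members of this list, and its score was higher in the IgG-PBS libraries (0.51 ± 0.116) than in the other groups (-0.13 ± 0.259 in IgG-IFNa). The mitochondrially encoded transcripts had a median of -0.77 over 15 with 0 past the edgeR threshold and 6 lower adjusted over the list alone (camera adjusted p = 1.12e-08, and adjusted p = 0.274 with an estimated correlation). That median was -0.34 without IgG-PBS library 3, which had 1.73% mitochondrial counts.

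Markers of other cells moved with this comparison too. Secretory epithelium markers had a median of 1.24 over 18 genes with Zg16 (2.30, SE 0.43) and Fcgbp (1.94, SE 0.37), goblet cell products, higher, or 5 adjusted over the list alone (camera adjusted p = 3.43e-10, and adjusted p = 0.205 with an estimated correlation). The median was 0.78 without IgG-PBS library 1. Zg16 did not pass without IgG-IFNa library 3 (2.08) or 4 (2.28) or IgG-PBS library 1 (1.99) or 2 (2.28), nor Fcgbp without IgG-IFNa library 2 (1.90), 3 (1.89) or 4 (1.92) or IgG-PBS library 1 (1.54) or 2 (1.91). Absorptive enterocyte markers had a median of 0.17 over 28 (camera adjusted p = 0.00178, and adjusted p = 0.596 with an estimated correlation). Their call was lost without IgG-IFNa library 1 (-0.035) or IgG-PBS library 1 (0.077), and the median was 0.26, 0.28 and 0.38 without IgG-IFNa library 2, 3 and 4 and 1.04 without IgG-PBS library 3. Myeloid markers had 0.41 over 21 (camera adjusted p = 0.0376, and adjusted p = 0.596 with an estimated correlation). Their call was lost without IgG-IFNa library 1 (0.31) or 3 (0.28), IgG-PBS library 1 (0.35) or 2 (0.47) or UC7-IFNa library 2 (0.41). Cytosolic ribosomal proteins had -0.096 over 75 (camera adjusted p = 0.0378, and adjusted p = 0.903 with an estimated correlation), lost without IgG-IFNa library 1 (-0.090) or 2 (-0.012) or IgG-PBS library 2 (-0.072) or 3 (-0.081). The ribosomal median was -0.21 without IgG-IFNa library 3.

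The other 17 lists did not pass after IgG. Their medians were 0.10 for gamma delta TCR constant regions and CD3, 0.011 for gamma delta variable segments, 0.041 for TCR proximal signalling, 0.063 for cytotoxic effectors, -0.090 for natural killer receptors, 0.24 for inhibitory receptors and -0.0023 for tissue residency. They were 0.064 for cell cycle, -0.079 for glycolysis, -0.041 for oxidative phosphorylation, 0.11 for the unfolded protein response, -0.44 for alpha beta T cells, 0.31 for B and plasma cells and 0.18 for innate lymphoid cells. Median and mean had opposite signs for cytokines and repair factors (-0.0077 and 0.013), apoptosis (-0.019 and 0.0035, test upward) and stroma (0.095 and -0.46, test downward). Single members fell in the TCR proximal list (Ubash3a, a phosphatase that restrains TCR signals, -1.39, SE 0.27) and among alpha beta T cell markers (Cd6, -1.32, SE 0.29). Ubash3a did not pass without IgG-IFNa library 3 (-1.36) or IgG-PBS library 1 (-1.44), 2 (-1.42) or 3 (-1.29), and Cd6 passed in 1 of the 13 single-library omissions (-1.57 to -0.96). Of the fixed genes, Trdc had -0.019 (SE 0.13), Trgc1 0.27 (SE 0.16), Trgc2 -0.083 (SE 0.12), Cd3e -0.22 (SE 0.21), Itgae 0.13 (SE 0.22), Cd8a 0.40 (SE 0.15), Gzma 0.31 (SE 0.20) and Gzmb 0.30 (SE 0.12), all with edgeR adjusted p of 0.295 or more.

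The rule also named H2bc4, H1f2, Sit1, Mmp11, Spin2c and Slc9a9, with log2 fold changes from -1.82 to -1.07. Spin2c (-1.23, SE 0.19) passed without any single library. H1f2 did not pass without IgG-PBS library 1 (-1.43) or 3 (-1.42). Mmp11 did not without IgG-IFNa library 2 (-1.19) or 3 (-1.14) or IgG-PBS library 1 (-1.40), 2 (-1.32) or 3 (-1.06). Sit1 did not without IgG-IFNa library 2 (-1.47), 3 (-1.50) or 4 (-1.33) or IgG-PBS library 1 (-1.65), 2 (-1.48) or 3 (-1.37). H2bc4 passed in 4 and Slc9a9 in 3 of the 13 omissions, with values from -2.21 to -1.67 and from -1.21 to -0.85. Between UC7-PBS and IgG-PBS, where no IFNa was given, some genes named for IFNa after IgG differed the same way without UC7-IFNa library 2. Values were -0.90 for Spin2c, -1.12 for H2bc4, 0.55 for Serpinb9, 2.46 for Zg16 and 2.02 for Fcgbp, none past the threshold. Jun (-1.24), Fos (-0.79), Zfp36 (-0.73), Myc (-0.71), Ifng (-0.70) and Ier5 (-0.61) also differed in the direction of their fall with IFNa, and did not pass either. Ifit3 (-1.08) and Gbp10 (-0.87) went against their rise with IFNa. Both comparisons use the IgG-PBS libraries. For genes that moved the same way, the level of those libraries cannot be told apart from a response to IFNa. The count of 131 depended on single libraries: it was 82, 35 and 45 without IgG-IFNa library 2, 3 and 4, 24, 37 and 25 without IgG-PBS library 1, 2 and 3, and 430 without UC7-IFNa library 2, which is in neither group compared but enters the shared spread and the filter (16224 genes tested without it). The male share as a covariate left 23 genes, all higher, and omission of the IgG-IFNa libraries with Y-linked transcripts left 21. The covariate with only UC7-IFNa library 2 left out gave 147 genes (122 higher and 25 lower), 90 of them among the 131. Of the 107 called genes outside the interferon and MHC class I lists, all 107 kept their sign without the IgG-IFNa libraries with Y-linked transcripts. The absence of overlap between the groups for called genes fixes that sign in advance. The median share of the fold change kept was 0.831 (quartiles 0.745 to 0.945). That share comes from libraries that also made the calls, so it cannot separate these genes from sex composition. The median ratio of their SE was 1.16, and 5 of them still passed.

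IFNa against PBS after UC7-13D5 asked the same question in mice whose gamma delta TCR was bound. Ifit3 rose from 2.25 ± 0.707 to 64.2 ± 23.5 CPM (n = 3 and 3), a log2 fold change of 4.84 (SE 0.36, edgeR adjusted p = 7.14e-06). Mx1 (ENSMUSG00000000386, chromosome 16, 97248235 to 97264107) rose from 0.764 ± 0.275 to 6.45 ± 0.350 CPM, by 3.07 (SE 0.45, edgeR adjusted p = 0.00296), and Irf7 from 122 ± 21.2 to 470 ± 80.3 CPM, by 1.94 (SE 0.17). Klrc1, the inhibitory receptor NKG2A (ENSMUSG00000030167, chromosome 6, 129642978 to 129655936), fell from 51.8 ± 24.6 to 14.4 ± 2.89 CPM, a log2 fold change of -1.85 (SE 0.37, edgeR adjusted p = 0.0474). Here 53 genes rose and 4 fell, 1202 had an unadjusted p under 0.05, and the groups did not overlap for any of the 57, nor for about 12% of tested genes, where chance gives 10%.

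Of the 53 antiviral genes 29 rose and none fell, and adjusted over the list alone 47 rose. The median was 1.70 (camera adjusted p = 1.28e-88, and adjusted p = 0.000887 with an estimated correlation). Oas3 rose by 4.04 (SE 0.47), Ifi27l2a by 3.71 (SE 0.40), Rtp4 by 2.90 (SE 0.23), Bst2 by 2.58 (SE 0.23), Oasl1 by 2.50, Rsad2, which makes an antiviral nucleotide, by 2.19 and Zbp1, a sensor of Z-form nucleic acid, by 2.12 (SE 0.19), and each passed without any single library. Ifi213 (3.32, SE 0.26) and Rnf213 (2.69, SE 0.21), outside the lists, did too. Isg15 rose by 1.26 (SE 0.23), but not without UC7-PBS library 1 (1.06) or 3 (1.21), and Ifit1 by 2.37, but not without UC7-PBS library 1 (2.20) or 3 (2.38).

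MHC class I antigen processing had a median of 0.38 with 2 of 23 higher, or 9 adjusted over the list alone (camera adjusted p = 1.01e-10, and adjusted p = 0.0071 with an estimated correlation). The 2 were H2-T23 (0.79, SE 0.14) and H2-T24 (1.96, SE 0.40). That median was 0.24 without UC7-IFNa library 2. The GTPases had 0.61 with Gbp10 (3.76, SE 0.44), Iigp1 (2.16, SE 0.36) and Gbp6 (1.85, SE 0.33) higher, or 10 of 16 adjusted over the list alone (camera adjusted p = 1.25e-12, and adjusted p = 0.209 with an estimated correlation). The GTPase score was 0.62 and 0.60 in UC7-IFNa libraries 1 and 3 but -0.41 in library 2, near the -0.62 to -0.47 of UC7-PBS, and the median was 0.74 without library 2. Interferon receptor signalling had 0.11 with 3 higher, among them Usp18 (3.26, SE 0.32) and Irf9 (1.60, SE 0.15), or 4 of 20 adjusted over the list alone (camera adjusted p = 1.17e-06, and adjusted p = 0.133 with an estimated correlation). The median of that list was 0.19 without UC7-IFNa library 2 and 0.18 without UC7-PBS library 3.

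Natural killer receptors had a median of -0.23 over 25 genes with 2 lower, or 5 adjusted over the list alone (camera adjusted p = 0.0364, and adjusted p = 0.209 with an estimated correlation). Klrc1 and Klrc2, which both pair with CD94, fell. Klrc2, the activating receptor NKG2C, went from 4.86 ± 0.421 to 0.909 ± 0.357 CPM (-2.41, SE 0.42). Klrc1 passed only in the omissions of UC7-PBS library 3 (-2.20) and IgG-IFNa library 4, and was between -1.94 and -1.61 in the 11 others. The list was lost without IgG-PBS library 1 or 2 (both -0.25), UC7-IFNa library 1 (-0.18) or 3 (-0.090) or UC7-PBS library 2 (-0.024) or 3 (-0.071), and was -0.40 without UC7-IFNa library 2.

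The TCR-induced early response list had a median of -0.11 over 35 genes with 1 lower, or 2 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.00924, and adjusted p = 0.419 with an estimated correlation). The 1 was Nfkbid, an atypical inhibitor of NF-kB induced by TCR signals, from 115 ± 21.0 to 46.8 ± 7.82 CPM (-1.29, SE 0.25). Nfkbid did not pass without IgG-PBS library 2 (-1.29), UC7-IFNa library 2 (-1.27) or 3 (-1.20) or UC7-PBS library 1 (-1.42), 2 (-1.15) or 3 (-1.30). The list was lost without UC7-IFNa library 1 (-0.054) or 3 (-0.030), was -0.31 without UC7-IFNa library 2, and was -0.071 and -0.17 without UC7-PBS library 1 and 3. Interleukin 15 signalling had 0.24 over 14 (camera adjusted p = 0.0199, and adjusted p = 0.306 with an estimated correlation), lost without UC7-IFNa library 2 (0.20) or 3 (0.26) or UC7-PBS library 2 (0.18) or 3 (0.22). Gamma delta TCR constant regions and CD3 had 0.18 over 10 (camera adjusted p = 0.0364, and adjusted p = 0.67 with an estimated correlation), lost without UC7-IFNa library 2 (-0.067) or UC7-PBS library 1 (0.12) or 3 (0.15), and 0.28, 0.29 and 0.30 without UC7-IFNa library 1 and 3 and UC7-PBS library 2. Single genes of that group did not pass: Trdc had -0.10 (SE 0.14), Trgc1 0.35 (SE 0.17), Trgc2 0.17 (SE 0.13), Cd3e -0.021 and Cd8a 0.43 (SE 0.16).

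Several groups moved with UC7-IFNa library 2, the library with 1.14% Rn18s. Oxidative phosphorylation had a median of 0.23 over 59 genes (camera adjusted p = 0.0158, and adjusted p = 0.768 with an estimated correlation), which turned to -0.19 without that library. It was lost without UC7-PBS library 1 (0.16) or 3 (0.20), and was 0.41 and 0.39 without UC7-IFNa library 1 and 3. Cell cycle genes had -0.13 over 32 (camera adjusted p = 0.0364, and adjusted p = 0.719 with an estimated correlation), lost without UC7-IFNa library 2 (-0.026) or UC7-PBS library 3 (-0.036), and -0.20 without UC7-IFNa library 3. Mitochondrially encoded transcripts had -0.49 over 15, with 1 lower adjusted over the list alone (camera adjusted p = 1.82e-08, and adjusted p = 0.419 with an estimated correlation), and -0.23, -1.12 and -0.27 without UC7-IFNa library 1, 2 and 3.

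Of the markers of other cells, secretory epithelium had -0.49 over 18 (camera adjusted p = 0.00011, and adjusted p = 0.43 with an estimated correlation), and -0.88 without UC7-IFNa library 2. Myeloid markers had 0.45 over 21, or 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00135, and adjusted p = 0.43 with an estimated correlation), lost without UC7-PBS library 3 (0.25). B and plasma cell markers had 0.57 over 10, or 1 higher adjusted over the list alone (camera adjusted p = 0.0364, and adjusted p = 0.43 with an estimated correlation). Their call was lost without IgG-IFNa library 1 (0.27), UC7-IFNa library 2 (0.11) or UC7-PBS library 1 (0.70) or 3 (0.65). The B cell median was 0.86 without IgG-PBS library 1 or 2, and 0.37 and 1.22 without UC7-IFNa library 1 and 3. The 57 called genes became 110 without UC7-IFNa library 2, 29 without UC7-PBS library 1 and 30 without UC7-PBS library 3. Among lists that did not pass, median and test differed in sign for inhibitory receptors (0.087, mean -0.094, downward), cytokines (0.041, downward), apoptosis (-0.025, upward), ribosomal proteins (0.14, downward) and stroma (0.022, downward). The heat-shock list had 0.20 here and did not pass (camera adjusted p = 0.957), and its median turned to -0.23 without UC7-IFNa library 2. With the male share as a covariate, which was at least 0.996 in every library of this arm, 53 genes passed (47 higher and 6 lower), 50 of them among the 57.

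The responses to IFNa in the arms, which share no library, were compared directly. Both arms called 31 genes, all 31 higher, 20 of them on the antiviral list, where independent lists of these sizes would share 0.328 higher genes. The lists were not independent, since both used the same spread per gene from the shared fit. All 57 genes called after UC7-13D5 had the same sign after IgG, and 127 of the 131 called after IgG had the same sign after UC7-13D5. Across all genes the log2 fold changes correlated at r = 0.224, or 0.191 without the antiviral list, and genes are not independent replicates.

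**Figure D3:**
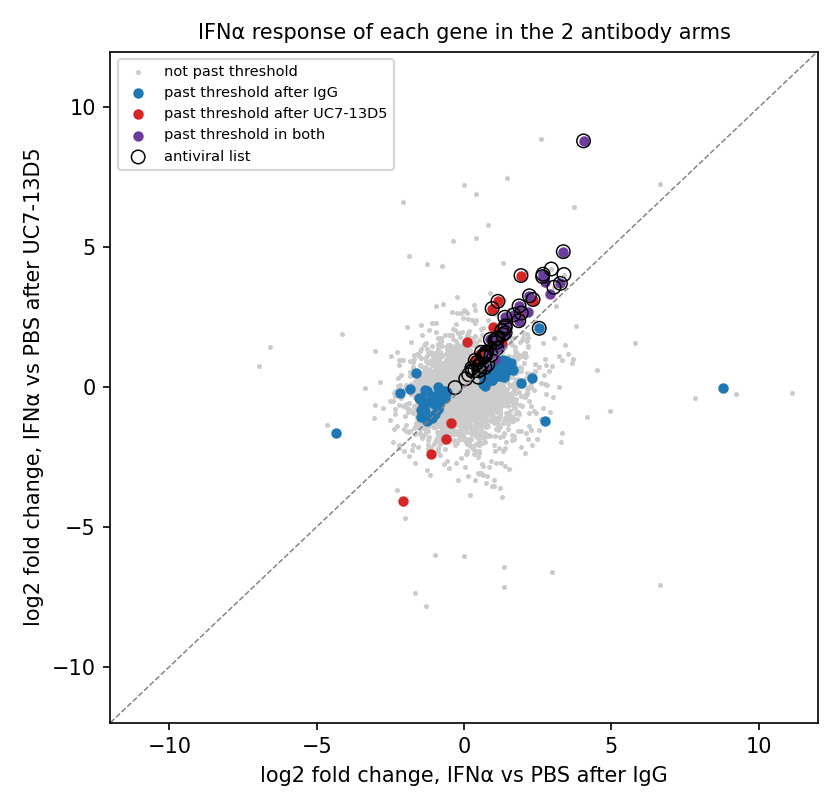
Log2 fold change of IFNa against PBS after IgG (horizontal) and after UC7-13D5 (vertical) for each tested gene, with the genes called in either arm and the antiviral list marked. The 31 genes called in both arms all lie to the upper right, and 50 of the 53 antiviral genes have the larger change after UC7-13D5.

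The interaction asked whether the response to IFNa differed between the antibodies. Of the 53 antiviral genes 50 had a larger change after UC7-13D5, with a median interaction of 0.52 log2 units (camera adjusted p = 2.66e-16, and adjusted p = 0.235 with an estimated correlation), and 0.37 with the male share as a covariate. Ifit3 had an interaction of 1.47 (SE 0.44), Mx1 1.91 (SE 0.58), Rtp4 1.03 (SE 0.30) and Xaf1 0.73 (SE 0.22), each with an edgeR adjusted p of 1. MHC class I antigen processing had 0.23 (camera adjusted p = 0.00608, and adjusted p = 0.239 with an estimated correlation), lost without IgG-PBS library 3 (0.20) and 0.11 without UC7-IFNa library 2. No single gene passed in edgeR, where 502 had an unadjusted p under 0.05, nor in limma voom with quality weights (0), while the DESeq2 Wald test called 5, and 1 passed in edgeR without UC7-PBS library 1. Among lists that did not pass, median and test differed in sign for the TCR-induced early response (0.077, downward), and median and mean for cytotoxic effectors (0.031 and -0.10), tissue residency (-0.091 and 0.015), B and plasma cells (0.20 and -0.066), myeloid cells (0.29 and -0.047) and stroma (-0.29 and 0.66).

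The dissociation and heat-shock list had a median interaction of 0.57 (camera adjusted p = 6.7e-13, and adjusted p = 0.235 with an estimated correlation), 0.36 without UC7-IFNa library 2, with the chaperone genes Dnajb1 at 1.76 and Hspa8 at 0.86 (edgeR adjusted p of 1). Secretory epithelium markers had -1.93, or 6 lower adjusted over the list alone (camera adjusted p = 5.22e-24, and adjusted p = 0.161 with an estimated correlation). The secretory median lay between -2.56 and -1.46 over the single omissions. The list's score was -2.48 in IgG-PBS library 1, against -0.28 and -0.31 in IgG-PBS libraries 2 and 3. Absorptive enterocyte markers had -0.32 (camera adjusted p = 9.93e-07, and adjusted p = 0.557 with an estimated correlation). The enterocyte median was -0.12 and -0.49 without IgG-IFNa library 1 and 4, -0.070 and -1.12 without IgG-PBS library 1 and 3, -1.03 and -0.18 without UC7-IFNa library 2 and 3, and -0.58 without UC7-PBS library 1. Oxidative phosphorylation had 0.26 (camera adjusted p = 0.000374, and adjusted p = 0.838 with an estimated correlation), which turned to -0.17 without UC7-IFNa library 2 and was 0.46 and 0.42 without UC7-IFNa library 1 and 3. Inhibitory receptors had -0.22 (camera adjusted p = 0.0352, and adjusted p = 0.244 with an estimated correlation), lost without IgG-IFNa library 2 (-0.14), IgG-PBS library 2 (-0.20) or 3 (-0.19), UC7-IFNa library 2 (-0.12) or UC7-PBS library 3 (-0.16), and -0.14 without IgG-IFNa library 3. Cell cycle genes had -0.19 (camera adjusted p = 0.0183, and adjusted p = 0.678 with an estimated correlation), lost without IgG-IFNa library 2 (-0.11), IgG-PBS library 3 (-0.15), UC7-IFNa library 2 (-0.15) or UC7-PBS library 3 (-0.14). Innate lymphoid markers had -0.38 over 7 genes (camera adjusted p = 0.0326, and adjusted p = 0.311 with an estimated correlation), lost without IgG-IFNa library 4 (-0.28), IgG-PBS library 1 (-0.48) or 3 (-0.47), UC7-IFNa library 2 (-0.40) or UC7-PBS library 1 (-0.023). The innate lymphoid median was -0.69 without IgG-PBS library 2, -0.82 and -0.72 without UC7-IFNa library 1 and 3, and -0.73 and -0.62 without UC7-PBS library 2 and 3.

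UC7-13D5 against IgG with PBS asked what binding of the receptor does without IFNa. The transcripts of the target did not differ beyond their spread: Trdc had a log2 fold change of 0.17 (SE 0.14), Trgc1 0.14 (SE 0.17), Trgc2 0.075 and Cd3e 0.11, each with an edgeR adjusted p of 1. The residency receptor Itgae had -0.011, Cd8a 0.032, Nr4a1 -0.42, Gzma 0.41 and Gzmb 0.26 (edgeR adjusted p of 1 each). The 1 gene past the threshold was Xist (ENSMUSG00000086503, chromosome X, 102503972 to 102526860), at 290 ± 36.2 CPM after IgG and 0.723 ± 0.471 CPM after UC7-13D5 (n = 3 and 3, fitted log2 fold change -8.66, SE 0.91, edgeR adjusted p = 0.00959). Xist did not pass without UC7-IFNa library 1, 2 or 3 or UC7-PBS library 2, its value staying between -9.07 and -8.19 over all 13 omissions. In edgeR 791 genes had an unadjusted p under 0.05, 4 genes passed without IgG-PBS library 3 and 2 without UC7-PBS library 1, and none passed without UC7-IFNa library 1 or 3 or UC7-PBS library 2. The DESeq2 Wald test called 69 genes and limma voom with quality weights 31. In the simulation of this contrast DESeq2 made 31 false calls, voom 3 and edgeR 7. The groups did not overlap for 12.4% of tested genes, where chance gives 10%.

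With PBS the heat-shock list had a median of -0.73 between the antibodies, with 0 of 23 past the edgeR threshold and 14 lower adjusted over the list alone (camera adjusted p = 3.51e-21, and adjusted p = 0.125 with an estimated correlation). Dnajb1, a co-chaperone, had -1.70 (SE 0.42), Jun -1.24 (SE 0.28), Hspa8, the constitutive heat-shock protein 70, -1.04 (SE 0.21) and Fos -0.79 (SE 0.16), with edgeR adjusted p from 0.196 to 0.353. The heat-shock median was -0.47 with the male share as a covariate. The antiviral list had -0.20 (camera adjusted p = 0.000512, and adjusted p = 0.8 with an estimated correlation), which turned to 0.28 with that covariate. Within a group the male share varied almost only in IgG-IFNa (0.0074 to 0.93). Values with the covariate therefore carry a difference under IFNa over to PBS. Cytotoxic effectors had 0.17 over 21, or 2 higher adjusted over the list alone (camera adjusted p = 0.0062, and adjusted p = 0.178 with an estimated correlation), lost without UC7-PBS library 2 (0.052) and 0.44 with the covariate. Its members with the smallest p were Lamp1, a lysosomal membrane protein, at 1.40 (SE 0.39), and Serpinb9 at 0.56 (SE 0.16). With PBS the TCR-induced early response list had a median of -0.22 over 35 genes. It fell just short of the threshold (camera adjusted p = 0.0508, and adjusted p = 0.8 with an estimated correlation). Klrc1 and Klrc2, which fell with IFNa after UC7-13D5, had 1.69 (SE 0.37, edgeR adjusted p = 0.269) and 1.53 (SE 0.39, adjusted p = 0.387) here. Secretory epithelium markers had 1.78, or 8 higher adjusted over the list alone (camera adjusted p = 3.91e-21, and adjusted p = 0.125 with an estimated correlation), and 1.15 without UC7-PBS library 1. Absorptive enterocyte markers had 0.66, or 5 higher adjusted over the list alone (camera adjusted p = 9.88e-14, and adjusted p = 0.395 with an estimated correlation), 0.37 and 1.43 without IgG-PBS library 1 and 3. Among lists that did not pass, median and test differed in sign for oxidative phosphorylation (0.015, downward) and B and plasma cells (0.077, downward), and median and mean for the unfolded protein response (-0.046 and 0.098) and stroma (0.14 and -0.096). Zg16 stood at 15.6 ± 7.71 CPM in IgG-PBS and 85.9 ± 37.8 CPM in UC7-PBS.

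UC7-13D5 against IgG with IFNa asked the same in mice given IFNa. Spp1, the secreted phosphoprotein osteopontin (ENSMUSG00000029304, chromosome 5, 104582984 to 104588916), was lower after UC7-13D5 at 55.2 ± 10.1 CPM against 137 ± 16.5 (n = 3 and 4, log2 fold change -1.32, SE 0.16, edgeR adjusted p = 0.00679). Rac1, a GTPase of the cytoskeleton (ENSMUSG00000001847, chromosome 5, 143489389 to 143513791), was higher at 257 ± 119 CPM against 58.1 ± 17.2 (2.14, SE 0.36, edgeR adjusted p = 0.0439). Snx20, a sorting nexin (2.29, SE 0.37), Arl8a, a lysosomal GTPase (1.87, SE 0.29), Srsf9, a splicing factor (1.74, SE 0.29), and Ctbp1, a transcriptional corepressor (1.59, SE 0.27), were higher too. Tmprss6 (-1.91, SE 0.32), the immunoglobulin delta gene Ighd (-1.69, SE 0.29), Capg, an actin-capping protein (-1.28, SE 0.22), and Xist (fitted -9.28) were lower. Outside the naming rule, and chosen after their values were seen, Map2 and the unnamed 2510039O18Rik completed the 12 genes, 6 higher and 6 lower. In edgeR 1138 genes had an unadjusted p under 0.05, and the groups did not overlap for any of the 12, nor for 6.78% of tested genes where chance gives 5.71%. Trdc had 0.093, Trgc1 0.23, Trgc2 0.33, Cd3e 0.30, Itgae -0.29 and Cd8a 0.059, none past the threshold.

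The 12 calls rested on single libraries. Their count was 43, 2, 2 and 2 without IgG-IFNa library 1, 2, 3 and 4, 4 and 2 without IgG-PBS library 2 and 3, 52, 2 and 0 without UC7-IFNa library 1, 2 and 3, and 2, 3 and 28 without UC7-PBS library 1, 2 and 3. Spp1 was lost only without UC7-IFNa library 3 (-1.19), and Xist only without UC7-IFNa library 2 or 3. Rac1, Arl8a, Srsf9 and Ctbp1 passed only without IgG-IFNa library 1, IgG-PBS library 1, UC7-IFNa library 1 or UC7-PBS library 3, and Snx20 also without IgG-PBS library 2. Over all omissions Rac1 stayed between 1.82 and 2.47, Snx20 between 1.89 and 2.63, Arl8a between 1.67 and 2.16, Srsf9 between 1.46 and 2.02 and Ctbp1 between 1.46 and 1.83. Tmprss6 (-2.17 to -1.64) and Ighd (-1.85 to -1.47) passed in 4 and Capg (-1.60 to -1.13) in 3 of the 13 omissions. With the male share as a covariate 5 genes passed (1 higher and 4 lower), 4 of them among the 12. All 11 called genes other than Xist had the same direction with PBS, 10 of them with an unadjusted p under 0.05 there.

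With IFNa the antiviral list had a median of 0.34 between the antibodies (camera adjusted p = 4.54e-11, and adjusted p = 0.625 with an estimated correlation), 0.22 without UC7-IFNa library 1 and 0.56 with the covariate. MHC class I antigen processing had 0.16 (camera adjusted p = 0.0477, and adjusted p = 0.625 with an estimated correlation) and lost its call without IgG-IFNa library 2 (0.14) or 4 (0.16), IgG-PBS library 2 or 3 (both 0.16), UC7-IFNa library 1 (0.19), 2 (0.039) or 3 (0.22), or UC7-PBS library 1 (0.15) or 3 (0.16). The TCR-induced early response list had -0.12, or 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0353, and adjusted p = 0.625 with an estimated correlation). It was lost without IgG-IFNa library 2 (-0.072), UC7-IFNa library 1 (-0.17) or 3 (-0.031) or with the covariate (-0.039), and was -0.18 without IgG-IFNa library 1 or 3 and -0.34 without UC7-IFNa library 2. Gamma delta TCR constant regions and CD3 had 0.24 (camera adjusted p = 0.0353, and adjusted p = 0.706 with an estimated correlation), lost without IgG-IFNa library 2 (0.20) or 4 (0.21), UC7-IFNa library 2 (-0.073) or with the covariate (0.16). Cell cycle genes had -0.18 (camera adjusted p = 0.0353, and adjusted p = 0.786 with an estimated correlation), lost without IgG-IFNa library 1 (-0.15) or 2 (-0.091), UC7-IFNa library 2 (-0.032) or with the covariate (0.10), and -0.29 without UC7-IFNa library 3.

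Oxidative phosphorylation had 0.26 with IFNa (camera adjusted p = 0.000965, and adjusted p = 0.84 with an estimated correlation) and turned to -0.16 without UC7-IFNa library 2. It was 0.45 and 0.41 without UC7-IFNa library 1 and 3, and lost with the covariate (0.18). Cytosolic ribosomal proteins had 0.29 (camera adjusted p = 0.00501, and adjusted p = 0.889 with an estimated correlation) and turned to -0.25 without UC7-IFNa library 2. They were lost without IgG-IFNa library 2 (0.19) or with the covariate (0.12), and were 0.51 and 0.47 without UC7-IFNa library 1 and 3. Mitochondrially encoded transcripts had 0.45 (camera adjusted p = 0.0328, and adjusted p = 0.84 with an estimated correlation), lost without IgG-IFNa library 2 (0.35) or 4 (0.40), UC7-IFNa library 2 (-0.14) or with the covariate (0.29), and 0.68 without UC7-IFNa library 1. Secretory epithelium markers had -0.37 (camera adjusted p = 0.0248, and adjusted p = 0.786 with an estimated correlation), lost without IgG-IFNa library 3 (-0.44) or UC7-IFNa library 1 (-0.27) or 3 (-0.32), and -0.24 and -0.82 without IgG-IFNa library 1 and UC7-IFNa library 2. Myeloid markers had 0.44 (camera adjusted p = 0.00256, and adjusted p = 0.625 with an estimated correlation), lost without IgG-IFNa library 4 (0.23) and 0.21 without UC7-IFNa library 2. Among lists that did not pass, median and test differed in sign for natural killer receptors (0.066, downward), tissue residency (0.031, downward), cytokines (0.088, downward) and apoptosis (-0.0070, upward), and median and mean for stroma (-0.067 and 0.57).

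The difference between antibodies averaged over PBS and IFNa was added after the data were seen, and the genes named here were chosen after their values were seen. It asked what binding of the receptor does whether or not IFNa was given. Here 87 genes were higher and 17 lower after UC7-13D5. Spp1 had -1.04 (SE 0.12, edgeR adjusted p = 0.00128), Snx20 2.14 (SE 0.27, adjusted p = 0.00395) and Rac1 1.94 (SE 0.26, adjusted p = 0.00538). Foxo1, a transcription factor of lymphocyte quiescence, had 1.32 (SE 0.19) and Dusp2, a phosphatase that restrains MAP kinases, 1.52 (SE 0.24). At an unadjusted p under 0.01, 247 autosomal genes differed with PBS and 329 with IFNa, and 75 did so in both, all 75 in the same direction, 67 higher and 8 lower. Independent lists of these sizes would share 5.30 of 15333. These lists were not independent, since both used the same spread per gene from the fit to all libraries. The groups compared with PBS and with IFNa share no library, and across autosomal genes their log2 fold changes correlated at r = 0.109.

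The DESeq2 Wald test called 296 genes and limma voom with quality weights 261. In edgeR the male share as a covariate left 1 of the 104 genes, Xist, and gave 15 genes with UC7-IFNa library 2 left out too (4 higher and 11 lower), 6 of them among the 104. Without that library and without the covariate edgeR called 78 genes higher and 37 lower. With the covariate the 103 called genes other than Xist all kept their sign, with a median of 1.09 of the fold change kept and 81 with an unadjusted p under 0.05. Their median SE was 0.21 without and 0.42 with the covariate, so the calls ended with a larger SE and not with a smaller fold. The male share was at most 0.00087 in IgG-PBS and at least 0.996 in the UC7-13D5 libraries, so covariate and antibody overlap. Such overlap enlarges the SE of the antibody difference. The fold kept rests on a slope taken almost only from the IgG-IFNa libraries, so it cannot separate these genes from sex. The count was 42, 60 and 41 without IgG-IFNa library 2, 3 and 4, 28 and 37 without IgG-PBS library 1 and 3, 41 without UC7-IFNa library 3, and 42 and 27 without UC7-PBS library 1 and 2. Of the lists, heat-shock had a median of -0.40 (camera adjusted p = 8.79e-11, and adjusted p = 0.536 with an estimated correlation), the TCR-induced early response -0.17 (camera adjusted p = 0.00797, and 0.726), cytotoxic effectors 0.083 (0.0200, and 0.536), gamma delta TCR constant regions and CD3 0.16 (0.0345, and 0.849) and the GTPases -0.12 (0.0345, and 0.859). Ribosomal proteins had 0.18 (camera adjusted p = 0.0200, and 0.859 with an estimated correlation), mitochondrial transcripts 0.30 (0.00695, and 0.859), enterocytes 0.53 (4.20e-08, and 0.726), secretory epithelium 0.47 (0.000143, and 0.822) and myeloid cells 0.31 (0.000947, and 0.726). No single omissions were run for these averaged lists. UC7-IFNa library 2 scored 0.55 against -0.056 and -0.041 in libraries 1 and 3 for TCR constant regions and CD3. For GTPases it scored -0.41 against 0.62 and 0.60, and for ribosomal proteins 0.86 against -0.41 and -0.23. For mitochondrial transcripts it scored 0.75 against -0.67 and -0.60. For heat-shock (0.37 against -0.51 and -0.29) and the early response (0.12 against -0.27 and -0.40) it lay against the averaged direction.

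**Figure D4:**
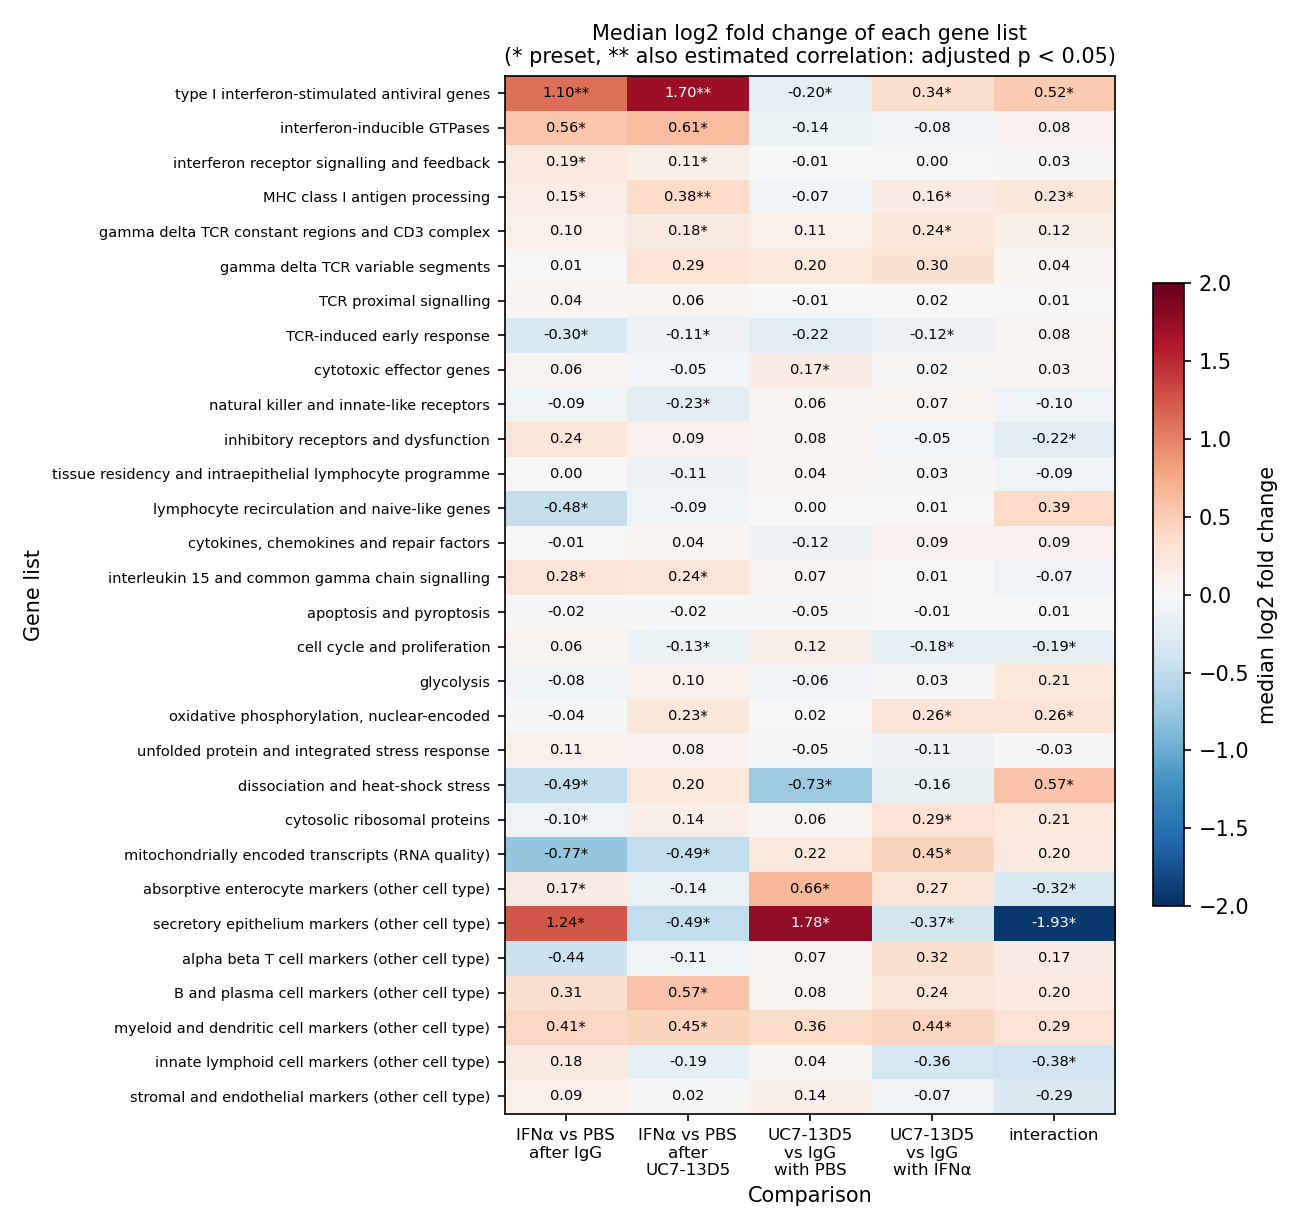
Median log2 fold change of each of the 30 lists (vertical) in each of the 5 comparisons (horizontal), as colour. A star marks lists past the camera threshold with the preset correlation (13, 14, 5, 10 and 9 lists) and a double star those also past it with an estimated correlation (1, 2, 0, 0 and 0).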

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

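The tests of sex composition (with the male share covariate), of the starting level, of handling stress and receptor blockade, of GC content and of the averaged difference with its splits were chosen only after the results were seen.

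The antiviral list had a median interaction of 0.52 log2 units, with more induction by IFNa after UC7-13D5, but camera lost the call with an estimated correlation (adjusted p = 0.235) and no single gene passed in edgeR. It was not made by UC7-IFNa library 2, since without it the median was 0.66. The IgG-IFNa libraries with Y-linked transcripts scored -0.35 relative to the others, and the median was 0.37 with the male share as a covariate. The list was lower in UC7-PBS than in IgG-PBS, by a median 0.38 times the size of the median interaction. With the covariate that difference turned to 0.28. The male share varied within a group almost only in IgG-IFNa, where IFNa was given. The 0.28 therefore carries a difference under IFNa over to PBS and does not decide about the starting level. Sex composition may share in the pattern, as may the starting level, and neither can be told apart from an effect of the antibody, because no IgG-PBS library with Y-linked transcripts gives that level.

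The dissociation and heat-shock list was lower in both comparisons against IgG-PBS, by medians of -0.73 (UC7-13D5 with PBS) and -0.49 (IFNa after IgG), with an interaction of 0.57, and camera lost all 3 calls with an estimated correlation (adjusted p = 0.125, 0.202 and 0.235). Stress of the IgG-PBS libraries in handling could give this shape, but without UC7-IFNa library 2 the list was also lower between the antibodies with IFNa, at -0.40. Blockade of the receptor could lower it between the antibodies too, yet only 0.212 of the difference with PBS was seen with IFNa, or 0.539 without UC7-IFNa library 2. Blockade cannot account for the -0.49 of IFNa after IgG, where no UC7-13D5 was given. There the level of the IgG-PBS libraries cannot be told apart from a response to IFNa. For the difference between the antibodies the 2 explanations cannot be told apart here, and isolation order was not given in the sources used here.

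Many genes that differed between UC7-13D5 and IgG with PBS did so the same way with IFNa: of 193 chosen on the PBS libraries, 152 had the same direction, 94 had an unadjusted p under 0.05, and the median share was 0.480 (0.340 to 0.680, an interval over genes that leaves out the spread between libraries). Between IgG-IFNa libraries with and without Y-linked transcripts the share was 0.0642 (0.0016 to 0.122, also over genes), so little of the difference was seen there. Those libraries are few, all were given IFNa, and those with Y-linked transcripts also held Xist. With PBS sex composition coincided with the antibody, so this share does not decide whether it made the difference. GC content had a rho of -0.065 with the difference with PBS, against 0.367 with IFNa and 0.111 there without UC7-IFNa library 2, so a trend with GC common to both is not seen, although genes higher in both had a median GC of 51.7% against 49.3%. Cohort, housing or strain of the mice, which may go with sex, was not tested and stays open beside the antibody.

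Splits of the same libraries gave as many genes only once of 35 for IFNa after IgG (131, highest other 1) and once of 35 for UC7-13D5 with IFNa (12, highest other 3), which is 1 split, the real one. The averaged difference gave 104 in 1 of 100 splits (highest other 1). For the interaction 100 of 100 splits gave as many as the 0 observed (highest other 3), which a count of 0 fixes in advance, so nothing follows from it. IFNa after UC7-13D5 and UC7-13D5 with PBS have only 10 splits, the real one being 1, which are too few.

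A gap test within the IgG-IFNa group, the only group with 4 libraries and the only one tested, singled out IgG-IFNa library 1 for Cd3e (gap over range 0.916), Ctbp1 (0.905) and Fcgbp (0.860), and IgG-IFNa library 4 for the MHC class I score (0.897). That is 4 of 78 tests, where chance gives 3.9, about 1 in 20 tests. Lists with an interaction past the camera threshold were antiviral (0.52), MHC class I (0.23), inhibitory receptors (-0.22), cell cycle (-0.19), oxidative phosphorylation (0.26), heat-shock (0.57), enterocytes (-0.32), secretory epithelium (-1.93) and innate lymphoid cells (-0.38), and none passed with an estimated correlation.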

How the results depend on the processing

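Alternatives moved the counts of called genes, and the cause was not tested except where given. For IFNa after IgG (131) the DESeq2 Wald test gave 406, limma voom with quality weights 374, only the groups compared 343, the male share covariate 23, omission of the IgG-IFNa libraries with Y-linked transcripts 21, and single omissions 24 to 430. For IFNa after UC7-13D5 (57) DESeq2 gave 141, voom 426, only the groups compared 22, omission of UC7-IFNa library 2 with the covariate 140, and single omissions 29 to 110. For UC7-13D5 with PBS (1) no filter gave 0, DESeq2 69, voom 31, only the groups compared 19, and single omissions 0 to 4. For UC7-13D5 with IFNa (12) DESeq2 gave 120, voom 70, only the groups compared 0, limma trend on the authors' normalized counts 2, the covariate 5, omission of the IgG-IFNa libraries with almost no Y-linked transcripts 3, omission of UC7-IFNa library 2 with the covariate 41, and single omissions 0 to 52. For the interaction (0) DESeq2 gave 5, the omission of IgG-IFNa libraries with almost no Y-linked transcripts 4, and single omissions 0 to 1.

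With an estimated correlation the list calls were 1 (of 13), 2 (of 14), 0 (of 5), 0 (of 10) and 0 (of 9) in the order IFNa after IgG, IFNa after UC7-13D5, UC7-13D5 with PBS, with IFNa, and interaction. With fry, tested for a shared direction, they were 4, 3, 0, 0 and 0 in the same order. After IgG these were the antiviral, interferon receptor, MHC class I and heat-shock lists, and after UC7-13D5 the first 3 of them. No list of the averaged difference passed directional fry (lowest fry adjusted p = 0.287). In the mixed form of fry, for changes in either direction, 15, 10, 1, 0 and 0 lists passed in the same order. For the averaged difference heat-shock, the early response and natural killer receptors passed it (mixed fry adjusted p = 0.00554 each). So did recirculation and cytokines (0.00848 each) and cytotoxic effectors (0.0453). List calls ranged from 7 to 15 over single omissions for IFNa after UC7-13D5, from 5 to 8 for UC7-13D5 with PBS (9 with the covariate) and from 6 to 12 with IFNa. Without UC7-IFNa library 2 the oxidative phosphorylation list turned negative, with single omissions from -0.19 to 0.41 (IFNa after UC7-13D5), from -0.16 to 0.45 (UC7-13D5 with IFNa) and from -0.17 to 0.46 (interaction), and so did the ribosomal list, from -0.25 to 0.51 (UC7-13D5 with IFNa). With the male share covariate, whose slope came almost only from the IgG-IFNa libraries, the antiviral list turned to 0.28 (UC7-13D5 with PBS).

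With the replicate number as a block the counts were 27 for IFNa after IgG, 34 for IFNa after UC7-13D5 and 1 for UC7-13D5 with IFNa. Of the lists, 6 of the 10 for UC7-13D5 with IFNa and 8 of the 9 for the interaction kept their call. Of 55 calls of genes chosen by size or fixed, 33 stayed with the block and 35 with the male share covariate. Libraries of the same number shared only a number: over 18 such pairs the mean correlation of residuals was -0.045, against 0.019 for different numbers, and 1 of 13 libraries correlated best with its own number.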

Other observations

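No test in this part was chosen only after the result was seen, but the 2 genes and the list were picked out after it. Klrc1 and Klrc2 stood higher in UC7-PBS (51.8 ± 24.6 and 4.86 ± 0.421 CPM) than in the other groups. With IFNa both fell after UC7-13D5. After IgG, Klrc1 had a log2 fold change of -0.60 (SE 0.34) and Klrc2 one of -1.13 (SE 0.38), neither past the threshold. Their interactions were -1.25 (SE 0.50) for Klrc1 and -1.28 (SE 0.56) for Klrc2, each with an edgeR adjusted p of 1, so a difference between the arms was not shown.

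The mitochondrial list and the percentage of mitochondrial counts were lower with IFNa in both arms, though camera lost the list with an estimated correlation (adjusted p = 0.274 after IgG and 0.419 after UC7-13D5). The percentage was 0.668 against 1.18 after IgG and 0.819 against 1.26 after UC7-13D5. UC7-IFNa library 2 had 1.23%, against 0.611% and 0.618% in UC7-IFNa libraries 1 and 3. Between the antibodies with IFNa the list had 0.45, -0.14 without that library, and camera lost that call too with an estimated correlation (adjusted p = 0.84).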
